A study of Mesocricetus auratus with 6 samples.

How the data were processed

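RNA was measured in the uterus of pregnant Syrian golden hamsters (Mesocricetus auratus) on day 5 of pregnancy, when blastocysts attach. Pieces of uterus that held an implanting embryo (implantation sites) were set against pieces of uterus between embryos (interimplantation sites). Each group had 3 arrays, each described in the labels as a biological replicate, and 6 arrays were used in all. The design text speaks of RNA from 3 animals, but no label names the animal of an array, so the p-values measure the spread between these arrays.

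Hamster RNA was hybridised to an Affymetrix array whose probes were designed on human transcripts. A probe set can therefore read a hamster transcript fully, weakly or not at all, depending on how far the 2 sequences match, and a dim probe set shows neither absence of the transcript nor absence of a change. The authors deposited 1 log2 value per probe set and array, made with RMA in Partek 6.6 per the submitters' processing notes. RMA subtracts background, brings all arrays to one distribution and summarises the probes of a set; its settings are not given in the sources used here. The base of the log is not stated either; the values of all arrays together ran from about 1.6 to 12.1, the range of log2 RMA values, and were read as log2. Array medians lay between 4.18 and 4.20, so a change of total RNA output per piece of tissue is not visible in these values. No scan date was used here, so no batch could be tested.

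The table held 22283 probe sets, of which 68 control probe sets were left out and 22215 were tested. Platform annotation gave 1 gene to 19065 of these, several genes to 1043 and none to 2107; the latter count among probe sets only. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 11963 genes, 4310 of them with several probe sets. Of these genes, 84.9% had a hamster gene of the same symbol in the RefSeq annotation of the assembly BCM_Maur_2.0, from which only names were taken. The text says where other probe sets of a named gene moved in the opposite direction with an unadjusted p under 0.05.

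Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 2 groups, no covariate), with Benjamini-Hochberg adjustment over probe sets or over genes and a threshold of 0.05. Differences are log2 implantation site minus interimplantation site, given with the standard error (SE) of limma's fit, and group means with the standard deviation (SD) over 3 arrays. The median SE over genes was 0.086. Adjusted p-values in the text are those of limma unless another test is named. The number of arrays limits the precision.

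Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives of the processing. There were 25 lists with 1132 genes, of which 982 were measured, 19 of them after an older symbol was updated. The proteasome, spliceosome, ubiquitin, tight junction and fatty acid lists take up themes known from the study of these samples, so their results are not independent evidence of those themes, although their members are textbook members and were not picked on these arrays. Each list was tested with limma's camera, which compares the members with all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 25 lists. Camera with a correlation estimated from the residuals and fry, which asks whether members move one way without comparing them with other genes, were alternatives. Members were counted past the threshold over all genes and adjusted over the list alone.

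Named genes were the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean was at or above the median of all probe sets, examples from each list by smallest p, and 28 candidate genes of implantation. Further list members that passed, and all genes named under the other observations, were named after their values were seen. Controls for RNA quality were the actin and GAPDH probe sets against the 3′, middle and 5′ parts of the transcript. Controls for hybridisation were the bacterial and phage RNAs bioB, bioC, bioD and cre. Both kinds were compared with exact permutation tests over the 10 splits of the arrays, two-sided, whose smallest possible p is 0.1.

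The fit was tested on simulated data for the comparison of 11963 genes with 200 genes changed and this number of arrays. It recovered 41.7% of 60 genes changed 1.25-fold, 100% of 70 changed 1.5-fold and 100% of 70 changed 2-fold, with 15 unchanged genes among 180 calls. With no gene changed it made 0 calls, and a list raised by 0.2 was the one list called. The changed genes were drawn from those at or above the median brightness, so recovery of dim genes was not tested. The noise was normal, with the spread of each gene as limma had already drawn it toward a common value. Spreads of real genes can vary more, and recovery can then be lower. The simulated noise was independent between genes, while the correlation estimated on these arrays was 0.068 for the proteasome and 0.288 for the ribosomal list. The simulation therefore cannot show how often camera calls a list of correlated genes wrongly. Alternatives covered the normalization, filters on dim probe sets, the spread model, array weights, the replicate number as a block, each array left out, the threshold, cross-hybridising probe sets and the probe set that stands for a gene. Figures were drawn with matplotlib 3.10.9.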

Results

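The uterus of the golden hamster was profiled on day 5 of pregnancy, with 3 arrays of implantation sites and 3 of interimplantation sites. The comparison asks which transcripts differ between uterus in contact with an embryo and uterus of the same stage without one. Arrays of the same group correlated at 0.989 to 0.995 over all probe sets and arrays of different groups at 0.985 to 0.992, so the ranges overlapped. No 2 arrays held the same values. Brightness varied little between arrays, with medians of 4.18 to 4.20, and the quartiles of the probe set means were 3.10 and 5.18.

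The largest rises at implantation sites were in follistatin and in single genes of the extracellular matrix (VCAN), cell division (CKS2), translation (EIF5A), protein folding (HSP90AA1) and nuclear transport (RAN). FST, whose product binds and blocks activins, rose most, from 7.28 ± 0.32 to 9.24 ± 0.06 (SD, n = 3 arrays per group), a 3.89-fold difference (log2 1.96 ± 0.13 SE, adjusted p = 6.0e-05), and both of its probe sets rose. VCAN, the matrix proteoglycan versican, was 2.76-fold higher (log2 1.47 ± 0.13 SE). Each gene is read here at its brightest probe set. Falls were fewer and by this reading smaller, led by HOXB6, a homeobox gene, HSPB1, a small heat shock protein, and SAT1, which acetylates spermidine and spermine. In all, 148 of 11963 genes passed the threshold in limma's test, 93 higher and 55 lower at implantation sites, and 1304 had an unadjusted p under 0.05.

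Among the other large rises CKS2, a subunit of cyclin-dependent kinases, was 2.55-fold higher (adjusted p = 0.00172). EIF5A, a translation factor that carries hypusine, rose 2.53-fold from a high level (9.50 ± 0.20 to 10.84 ± 0.08, SD, n = 3; adjusted p = 8.5e-05). HSP90AA1, a cytosolic chaperone, rose 2.40-fold, and RAN, the GTPase of nuclear transport, rose 2.36-fold. The histone variant gene H2AZ1 and LOXL1, a lysyl oxidase that cross-links elastin, were each 2.12-fold higher. TUBA1B (alpha-tubulin), PSME3 (a proteasome activator), FBLN1 (the matrix protein fibulin 1) and HNRNPD (an RNA-binding protein) completed the 12 largest rises, with log2 differences of 0.99, 0.94, 0.92 and 0.90. Of the 4 probe sets of HSP90AA1, 1 passed an unadjusted p of 0.05. The evidence on HNRNPD was mixed, since 3 of its 6 probe sets were higher and 1 was lower by a similar amount (log2 −0.90). Each of these 12 genes stayed past the threshold whichever array was left out, but FBLN1 (log2 0.22) and HNRNPD (0.30) did not pass when the mean of a gene's probe sets was tested.

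HOXB6 fell 2.08-fold (log2 −1.05 ± 0.14 SE, adjusted p = 0.00308) and HSPB1 2.06-fold (log2 −1.04 ± 0.14 SE, adjusted p = 0.00394). SAT1 fell 1.99-fold and SRSF7, a splicing factor, 1.90-fold. ATP1B1, the beta subunit of the sodium-potassium pump, fell at both of its probe sets, with log2 differences of −0.83 at the brighter one and −2.03 at the other, which had the smallest p and the largest difference of all probe sets. GLUL (glutamine synthetase), ITM2B and IVNS1ABP fell by 0.84, 0.82 and 0.81 on the log2 scale. SOX17, a transcription factor of endoderm, uterine epithelium and vessels, fell by 0.78 and KDM6A, a histone demethylase, by 0.73. ZBTB20, a transcriptional repressor (log2 −0.84, adjusted p = 0.0369), and ACTG2, smooth muscle gamma-actin (log2 −0.80, adjusted p = 0.0392), were the least firm of the 12. Both missed the threshold without any 1 of 5 of the 6 arrays (adjusted p up to 0.129 and 0.127), IVNS1ABP without any 1 of 4 (up to 0.0808), and ATP1B1 without interimplantation site 3 (0.0638). ACTG2 also missed it with the replicate number as a block (adjusted p = 0.0677). With the mean of a gene's probe sets SAT1 (log2 −0.37), SRSF7 (−0.17), GLUL (−0.41), ZBTB20 (−0.05), IVNS1ABP (−0.44), KDM6A (−0.30) and ACTG2 (−0.80, adjusted p = 0.0697) did not pass.

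**Figure D1:**
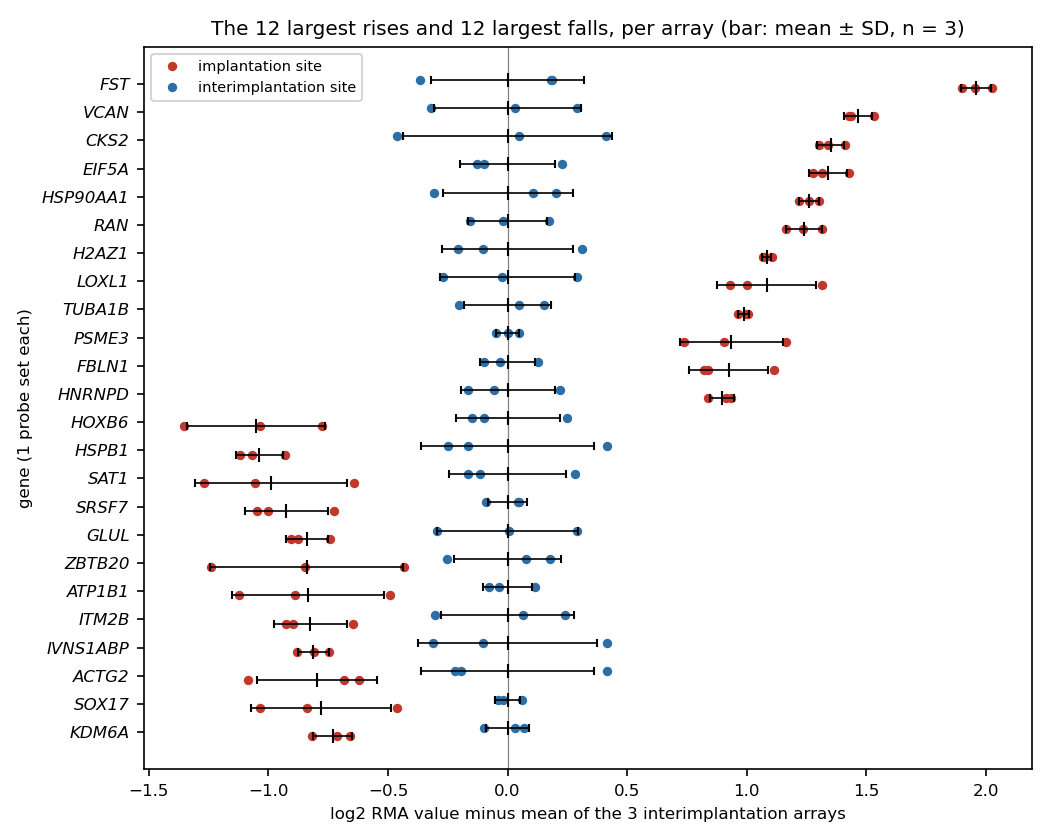
Log2 RMA value of each of the 6 arrays, minus the mean of the 3 interimplantation arrays of that gene, for the 12 largest rises and 12 largest falls; points are arrays, bars are means ± SD (n = 3). The groups do not overlap in any of these genes, and FST shows the largest difference (log2 1.96).

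Differences were small for most genes. Of the 148 genes, 47 were at least 1.5-fold higher and 24 at least 1.5-fold lower, and 8 and 2 reached 2-fold; 95% of all genes differed by less than 1.20-fold. The groups did not overlap in 1968 genes, or 16.5%, against 10% by chance. Among single probe sets, 235 of 22215 passed, 156 higher and 79 lower, with 83 to 140 higher and 33 to 90 lower when single arrays were left out. Of the genes that passed, 86.5% had a brightness at or above the median probe set, each gene being read at its brightest probe set. The count of higher genes fell from 93 to 60 without implantation site 1 and to 50 without interimplantation site 3. The count of lower genes fell from 55 to 26 without implantation site 1, to 26 without implantation site 3, to 27 without interimplantation site 2 and to 25 without interimplantation site 3.

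Among the gene lists, the proteasome and proliferation lists shifted up most. Of 39 measured proteasome genes, 6 rose and 0 fell (14 and 0 adjusted over the list alone): PSME3, PSMD1 (log2 0.76), PSMA7 (0.67), PSMB7 (0.64), PSMB3 (0.62) and PSMA3 (0.54), which span the core particle, the regulatory particle and an activator. The median over the list was 0.14 (camera adjusted p = 3.44e-10), but the adjusted p was 0.170 with an estimated correlation. Of 59 proliferation genes, 3 rose and 0 fell (13 and 0 adjusted over the list alone): CKS2, CCNA2 (cyclin A2, log2 0.80 ± 0.11 SE) and PCNA (the DNA polymerase clamp, log2 0.54 ± 0.09 SE). Their median was 0.12 (camera adjusted p = 5.87e-09; adjusted p = 0.0769 with an estimated correlation). Among ubiquitin enzymes, UBE2S, UBE2K, UCHL3 and CUL2 rose, 4 of 51 measured with 0 that fell (8 and 1 adjusted over the list alone), with log2 differences of 0.75, 0.56, 0.51 and 0.42. Their median was 0.05 (camera adjusted p = 0.00313; adjusted p = 0.357 with an estimated correlation), and the call was lost without interimplantation site 3 (adjusted p = 0.0628). The proteasome and ubiquitin lists follow themes of the study itself and are not independent evidence. PCNA and PSMB3 missed the threshold without any 1 of 2 arrays (adjusted p up to 0.0850 and 0.0799), UCHL3 without any 1 of 5 (up to 0.122), and CUL2 without any 1 of the 6 (up to 0.127) and with the replicate number as a block (0.0508). PCNA was also dim, with means of 2.78 at implantation and 2.24 at interimplantation sites, under the first quartile of 3.10. UCHL3 (3.76 and 3.25) lay under the median brightness of 4.19. PSMA7 (log2 0.32) did not pass without cross-hybridising probe sets, nor CCNA2 (0.41) and CUL2 (0.19) with the mean of a gene's probe sets.

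Splicing genes went both ways. Of 86 measured spliceosome genes, HNRNPD, SRSF1 (log2 0.81), HNRNPA2B1 (0.68) and SRSF3 (0.65, adjusted p = 0.0531 without 1 of the arrays) rose and SRSF7 (−0.93) fell; adjusted over the list alone 9 rose and 2 fell. SRSF5, a splicing factor of the same family as SRSF7, was at −0.47 and did not pass, except with array weights (−0.52, adjusted p = 0.0382). The list median was 0.06 (camera adjusted p = 0.00486; adjusted p = 0.348 with an estimated correlation), with an adjusted p of 0.0708 without implantation site 1 and 0.0621 without interimplantation site 1. This list, too, follows a theme of the study and is not independent evidence. Of 43 genes of endoplasmic reticulum folding and stress, HSPA5 (the chaperone BiP, log2 0.43 ± 0.09 SE) rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.00013; adjusted p = 0.348 with an estimated correlation). HSPA5 missed the threshold without any 1 of 5 of the 6 arrays (adjusted p up to 0.175). It was also dim, with means of 3.75 at implantation and 3.31 at interimplantation sites, under the median brightness of 4.19.

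Ribosomal protein genes were the one list that shifted down. Of 52 measured, 0 passed in limma's test over all genes, 1 higher and 7 lower had an unadjusted p under 0.05, and adjusted over the list alone 0 rose and 1 fell. RPS27 (log2 −0.35 ± 0.08 SE) and RPS19 (log2 −0.37 ± 0.10 SE) had the smallest p among the lower members. After repeated quantile normalization both passed, at −0.61 (adjusted p = 0.00170) and −0.62 (0.00169), and with array weights as well (adjusted p = 0.0456 and 0.0452). RPS27 also passed after cyclic loess (0.0433), with either filter on brightness (0.0447 and 0.0270) and with a random replicate block (0.0467). The median was −0.08 (camera adjusted p = 0.0032; adjusted p = 0.546 with an estimated correlation), and the adjusted p was 0.578 without interimplantation site 2. For 53 genes of oxidative phosphorylation the median was 0.05 (camera adjusted p = 0.0464; adjusted p = 0.357 with an estimated correlation), with 0 genes past limma's threshold over all genes, 1 higher adjusted over the list alone, and 6 higher and 1 lower at an unadjusted p under 0.05. ATP5MC3, a subunit of ATP synthase (log2 0.41), passed with either filter on brightness (adjusted p = 0.0454 and 0.0285) and with a random replicate block (0.0474). The call of the oxidative phosphorylation list was lost without any 1 of 4 arrays, with the highest adjusted p, 0.374, without interimplantation site 1. It was also lost after repeated quantile normalization (camera adjusted p = 0.0687) and cyclic loess (0.0557). Camera placed 6 of 25 lists higher and 1 lower, and none held with an estimated correlation. Actin signal from the 3′ end relative to the 5′ end, an RNA quality measure, also differed between these arrays, at −2.08 ± 0.22 in implantation sites and −1.70 ± 0.15 in interimplantation sites (log2, SD, n = 3; exact permutation p = 0.1, the smallest possible).

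**Figure D2:**
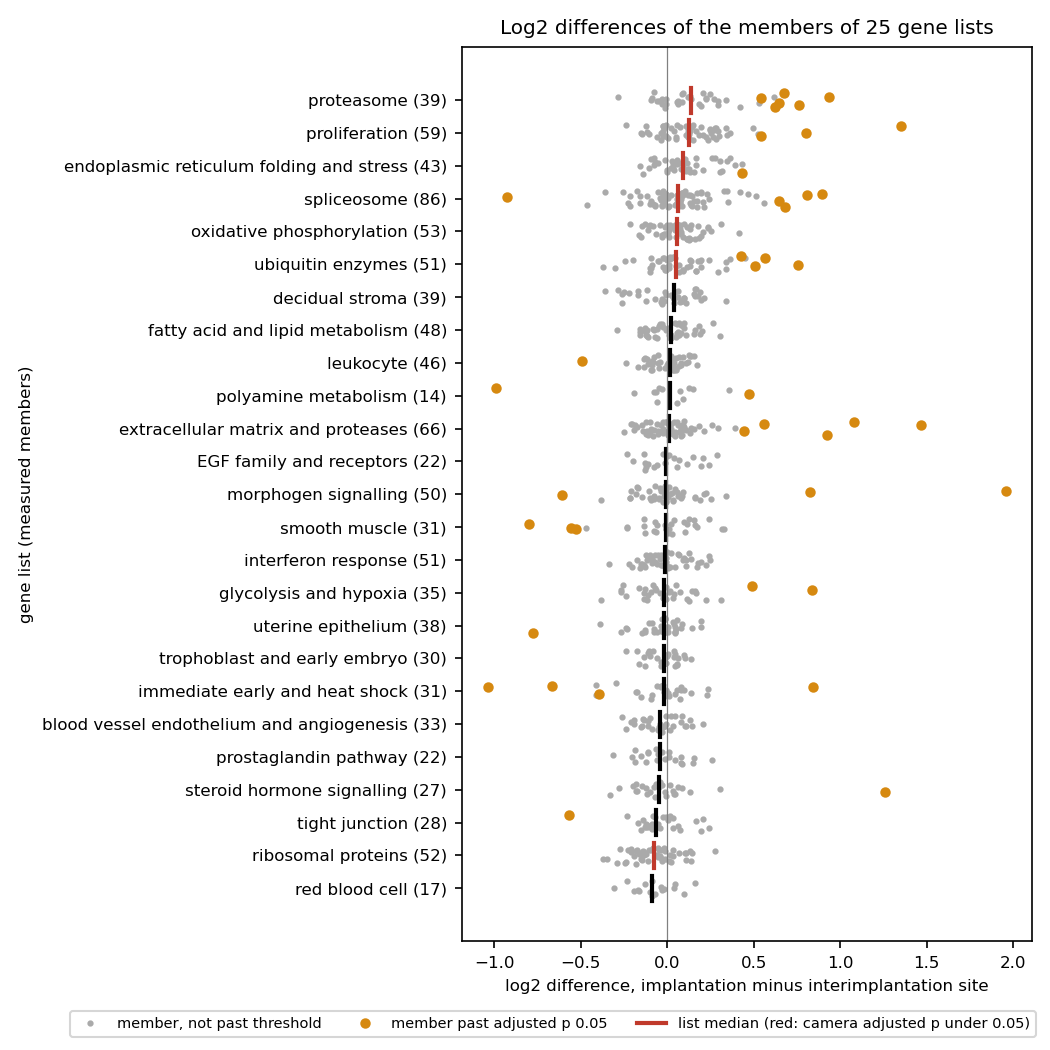
Log2 difference, implantation minus interimplantation site, of each measured member of 25 gene lists (grey points; orange points passed an adjusted p of 0.05 over all genes) with the list median as a bar, red where camera's adjusted p was under 0.05. Proteasome (median 0.14) and proliferation (0.12) genes lie farthest to the right, and in the matrix list single genes such as VCAN stand far from a median near 0.

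Several matrix genes rose, while tests of the matrix list disagreed. VCAN, LOXL1, FBLN1, COL1A1 (log2 0.56 ± 0.09 SE) and LOX (log2 0.45 ± 0.08 SE) rose and 0 of the 66 measured members fell (7 and 0 adjusted over the list alone), while the list median was 0.01 (camera adjusted p = 0.147; fry adjusted p = 0.0376, higher). COL1A1 did not pass after repeated quantile normalization (log2 0.28) or without cross-hybridising probe sets (0.24), nor with the mean of its probe sets (0.28). LOX, a cross-linking enzyme of collagen and elastin, missed the threshold without any 1 of 4 arrays (adjusted p up to 0.112) and was at 0.14 with the mean of its probe sets (adjusted p = 0.540). In morphogen signalling, FST and FZD2 (a WNT receptor, log2 0.83 ± 0.10 SE) rose and JAG1 (a Notch ligand, log2 −0.61 ± 0.11 SE) fell, out of 50 (2 and 2 adjusted over the list alone; camera adjusted p = 0.900). JAG1 missed the threshold without any 1 of 3 arrays (adjusted p up to 0.0847) and without cross-hybridising probe sets (log2 −0.20) or with the mean of its probe sets (−0.26). Of 35 genes of glycolysis and hypoxia, PGK1 (log2 0.83 ± 0.13 SE) and GAPDH (log2 0.49 ± 0.08 SE), enzymes of adjacent steps, rose and 0 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.962), and neither passed with the mean of a gene's probe sets (0.34 and 0.35). MXI1, a repressor of the MYC network (log2 −0.38), passed among probe sets at or above the median brightness (adjusted p = 0.0447) and with a random replicate block (0.0474).

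Stress genes moved in opposite directions. Among 31 immediate early and heat shock genes, HSPD1, the mitochondrial chaperonin, rose (log2 0.85 ± 0.09 SE), while HSPB1, GADD45A (log2 −0.66 ± 0.13 SE) and JUND (log2 −0.40 ± 0.08 SE) fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.265; fry adjusted p = 0.0312, lower). GADD45A missed the threshold without any 1 of 5 arrays (adjusted p up to 0.0863) and JUND without any 1 of 6 (up to 0.162). With the replicate number as a block neither passed (adjusted p = 0.0552 and 0.0700), nor with the mean of a gene's probe sets, where GADD45A was unchanged (adjusted p = 0.0520) and JUND was at −0.17 (0.447). Of 14 genes of polyamine metabolism SAT1, a catabolic enzyme, fell and ASS1, which makes the arginine precursor argininosuccinate, rose (log2 0.47 ± 0.07 SE; 2 and 1 adjusted over the list alone; camera adjusted p = 0.623). Of 27 genes of steroid hormone signalling the chaperone HSP90AA1 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.540). TJP1, the scaffold protein ZO-1, fell among 28 tight junction genes (log2 −0.57 ± 0.08 SE; 0 and 1 adjusted over the list alone; camera adjusted p = 0.253; fry adjusted p = 0.0312, lower), a list that follows a theme of the study, and did not pass with the mean of its probe sets (−0.31). In 4 further lists 0 genes passed in limma's test, over all genes or adjusted over the list alone. Of 48 genes of fatty acid and lipid metabolism, a theme of the study as well, 3 were higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.715). The lower one, APOE (apolipoprotein E), was lower at all 3 of its probe sets. It was at −0.29 at the brightest, passed with the mean of them (−0.45, adjusted p = 0.0391) and with the most variable one (−0.79, adjusted p = 0.000860). ACLY, which makes acetyl-CoA (log2 0.31), passed with the stricter filter on brightness (adjusted p = 0.0408). The counts at an unadjusted p under 0.05 were 1 and 2 of 22 in the prostaglandin pathway (camera adjusted p = 0.522), 4 and 1 of 22 in the EGF family (0.784) and 6 and 2 of 51 in the interferon response (0.784).

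Camera called none of the lists of markers for cell types that a piece of uterus can hold, while fry placed the endothelium list lower (adjusted p = 0.0312). Smooth muscle genes had 3 falls among 31, in ACTG2, TAGLN (log2 −0.56 ± 0.11 SE) and MYLK (log2 −0.53 ± 0.11 SE), which encode contractile proteins and their kinase, and 0 rises (2 rises and 5 falls adjusted over the list alone; camera adjusted p = 0.715). The bright muscle genes ACTA2 and MYH11 were at 0.15 and 0.00, although a dimmer probe set of MYH11 was at −0.35 (unadjusted p = 0.00943 over probe sets). Each of the 3 falls was lost without any 1 of 5 of the 6 arrays (adjusted p up to 0.127, 0.145 and 0.188). MYLK also missed the threshold after cyclic loess (0.0513), after median centring (0.0528), without cross-hybridising probe sets (0.0515) and with the mean of a gene's probe sets (0.0677). In the last 2 its 1 probe set was unchanged (log2 −0.53), and only the fit and adjustment over the other genes differed. SOX17 fell among 38 epithelial genes (0 and 1 adjusted over the list alone; camera adjusted p = 0.385). Among 46 leukocyte genes SPI1, a myeloid transcription factor, fell (log2 −0.49 ± 0.10 SE; 0 and 1 adjusted over the list alone; camera adjusted p = 0.997). SPI1 missed the threshold without any 1 of 5 arrays (adjusted p up to 0.132). It also missed it with the mean of a gene's probe sets (0.0520), although its 1 probe set was unchanged there. In the other marker lists 0 genes passed in limma's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 decidual stroma genes were higher and 4 lower of 39 (camera adjusted p = 0.784), 1 and 4 of 33 for endothelium (0.258), 0 and 3 of 17 for red blood cells (0.0969) and 0 and 1 of 30 for trophoblast and early embryo (0.522). In 5 lists without a call, the EGF family, morphogen signalling, leukocyte, glycolysis and polyamine lists, the median, the mean and camera's direction did not all have 1 sign.

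Candidate genes known from implantation in rodents were nearly all within the error. Of 28 candidates 25 were measured, and SAT1 was the one that passed, lower at implantation sites (0 higher and 1 lower adjusted over the list alone). HAND2, a stromal transcription factor that responds to progesterone, was at 0.18 ± 0.08 (SE), CALCA, which encodes calcitonin, at 0.20 ± 0.09 and ISG15, a ubiquitin-like protein induced by interferon, at −0.22 ± 0.08, each with an unadjusted p under 0.05 and short of the adjusted threshold. HBEGF (log2 0.07 ± 0.10 SE), LIF (−0.15 ± 0.09), BMP2 (0.16 ± 0.15), WNT4 (0.21 ± 0.13) and PTGS2 (−0.01 ± 0.08) did not differ by more than about 2 SE. Of the 25, 9 lay below the median brightness, and 4 of them, such as PTGS2 with a mean of 2.63 at implantation sites and MSX1 with 2.76, lay under the first quartile.

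Control probe sets for actin and GAPDH read higher in implantation sites at the middle and 5′ parts of the transcript, where GAPDH passed in limma's test (adjusted p = 0.00172 and 0.0131 over 68 control probe sets). The 5′ probe set of actin read 9.72 ± 0.23 in implantation sites and 9.28 ± 0.20 in interimplantation sites (SD, n = 3), while the 3′ probe set read 7.65 ± 0.04 and 7.58 ± 0.06. The GAPDH difference between 3′ and 5′ was −0.20 ± 0.16 in implantation sites and 0.13 ± 0.17 in interimplantation sites (log2, SD, n = 3; exact permutation p = 0.2). The hybridisation control RNAs (bioB, bioC, bioD and cre) averaged 7.26 ± 0.22 and 7.57 ± 0.25 (exact permutation p = 0.3, n = 3). Since human probes at the ends of a transcript match hamster RNA to different degrees, the sign of a 3′ to 5′ difference is no measure of integrity here, and only its difference between arrays can be read.

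**Figure D3:**
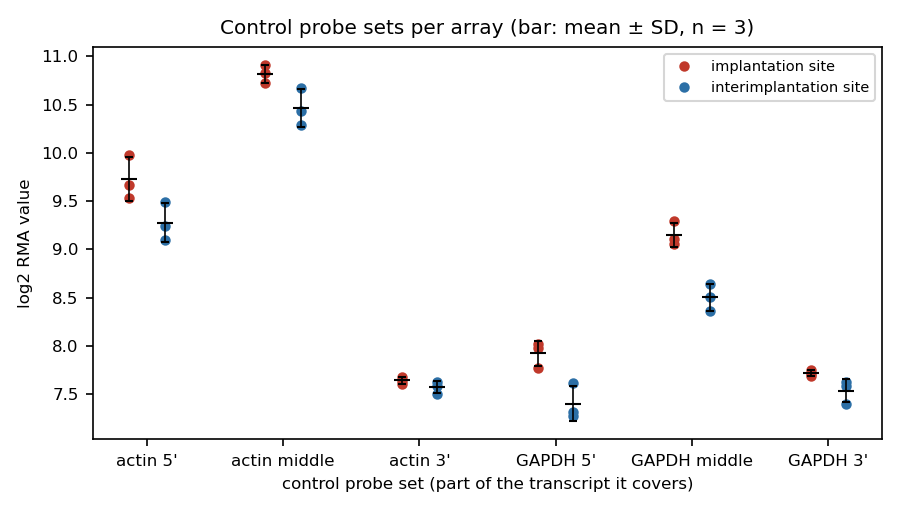
Log2 RMA values of the control probe sets for actin and GAPDH on each array (red, implantation sites; blue, interimplantation sites), with mean ± SD (n = 3) as bars. The 5′ and middle probe sets read higher in implantation sites, by 0.45 and 0.36 for actin and 0.52 and 0.65 for GAPDH, and the 3′ probe sets by 0.07 and 0.18.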

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

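The limma test of the control probe sets and their values under other scalings were chosen after the results were seen.

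The GAPDH control probe sets read higher at implantation sites, in data outside the measured genes. The probe set for the middle of the transcript differed by 0.645 on the log2 scale (9.15 ± 0.12 against 8.51 ± 0.14, SD, n = 3; limma's adjusted p = 0.00172 over 68 control probe sets), with 3 of 3 implantation arrays above the others. The probe set for the 5′ part differed by 0.52 (adjusted p = 0.0131). Under 3 other scalings of the arrays the middle probe set lay between 0.53 and 0.65 and the 5′ probe set between 0.50 and 0.52. The probe set for the 3′ part differed by 0.18 and did not pass (adjusted p = 0.198). The gene GAPDH itself rose by 0.49 at another probe set and did not pass with the mean of its probe sets (0.35, adjusted p = 0.0623). Whether the level of GAPDH or the quality of the RNA differed stays open and was not tested. Actin control probe sets were higher too, at 0.45 for the 5′ part and 0.36 for the middle, without passing (adjusted p = 0.0812 for each).

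A difference in array quality could mimic the shift of proteasome and proliferation genes, since the control transcripts moved with the groups. A bias that depends on brightness is argued against, because the median of the 98 genes together (0.126) lay at percentile 100 of 10000 random lists matched on brightness, whose central 95% ran from −0.033 to 0.021. With the actin 3′ to 5′ difference of each array as a covariate, the mean of the genes still differed by 0.132 between groups (95% interval 0.061 to 0.203, against 0.179 without it). This cannot decide whether RNA integrity was the cause. The covariate itself separated the groups, at −2.33 to −1.92 in implantation sites and −1.87 to −1.59 in interimplantation sites. It also rests on 1 pair of probe sets, whose error can leave a group difference in place. With the level of the hybridisation control RNAs as a covariate the difference was 0.154 (0.078 to 0.230). This cannot decide whether the amount of labelled RNA was the cause either. These controls averaged 7.26 in implantation sites and 7.57 in interimplantation sites, and error in them can also leave a group difference in place. Contact with the embryo, the difference that the design names, stays open and was not tested apart from other differences between the pieces of tissue, such as their position and composition.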

How the results depend on the processing

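All alternatives here were planned before the data were examined; the genes named beyond the rule were added to them later. FST, VCAN, EIF5A and RAN kept direction and call under every alternative. The proteasome, proliferation and endoplasmic reticulum lists kept theirs under each normalization, the filter at the median brightness, the fixed replicate block and each left-out array. These lists lost the call with an estimated correlation, and the last also under fry. No list was run with the stricter filter on brightness or with a random block. Of the genes called, cyclic loess shared 138 of its 140 calls with the 148 reported, repeated quantile normalization 142 of 161, the fit without cross-hybridising probe sets 123 of 126 the mean of a gene's probe sets 83 of 99 and the most variable probe set 136 of 173. Of the reported calls, TUBB had the opposite sign without cross-hybridising probe sets and HNRNPD and ZBTB20 with the most variable probe set, none past the threshold there. The mean of probe sets ended 33 calls of named genes, and the replicate block 4 (ACTG2, CUL2, GADD45A and JUND). Among 76 named genes past the threshold, 49 stayed past it whichever array was left out. Of the genes that passed, 86.5% lay at or above the median of all probe sets. Each gene is read at its brightest probe set, and the share over all genes was not computed. The figure alone therefore does not show how far brightness limited the calls. For the changes that follow, the cause was not tested.

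Whether the replicate numbers pair the arrays stays open. Deviations from the group means correlated at −0.002 to 0.070 between arrays of the same number and at −0.069 to 0.017 between others; among brighter probe sets the ranges were 0.027 to 0.066 and −0.045 to −0.003. With the replicate number as a block, 97 genes were higher and 66 lower (128 of 163 shared with the reported calls), and 159 and 93 probe sets. As a random block it gave 111 and 75 genes. The block turned the direction of the leukocyte list (adjusted p = 0.945) and changed no list's call.

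With an unadjusted p under 0.05 and 1.5-fold, 54 genes were higher and 27 lower, and 88 and 48 probe sets. Array weights gave 96 lower genes and 133 lower probe sets, and the mean of a gene's probe sets 26 lower genes. With arrays left out singly or by number, higher genes ranged from 32 to 89, lower genes from 11 to 65, higher probe sets from 34 to 140 and lower probe sets from 11 to 90.

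With an estimated correlation the adjusted p was 0.0769 for proliferation, 0.170 for the proteasome, 0.348 for the spliceosome and the endoplasmic reticulum, 0.357 for ubiquitin enzymes and oxidative phosphorylation, and 0.546 for ribosomal proteins. Fry, which compares no list with other genes, gave 0.0968 for the endoplasmic reticulum, 0.125 for the spliceosome and ubiquitin enzymes, 0.248 for oxidative phosphorylation and 0.326 for ribosomal proteins. It newly passed the tight junction, endothelium and immediate early lists (0.0312 each) and the matrix list (0.0376), and turned the leukocyte list (0.875). Oxidative phosphorylation was at 0.0687 after quantile normalization and 0.0557 after cyclic loess, which also turned the leukocyte list (0.992). Among genes at or above the median brightness, immediate early and heat shock genes passed (0.0384). There the decidual, steroid, interferon and lipid lists (0.903 each), smooth muscle (0.966) and glycolysis (0.680) turned direction. With the mean of a gene's probe sets the EGF and glycolysis (0.847 each), morphogen (0.906) and lipid (0.965) lists turned.

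With arrays left out, the adjusted p ranged from 0.000743 to 0.0708 for the spliceosome, 0.000102 to 0.0628 for ubiquitin enzymes, 1.63e-06 to 0.578 for ribosomal proteins and 0.00509 to 0.374 for oxidative phosphorylation. Lists without a call that turned direction had ranges of 0.605 to 0.980 (decidual), 0.635 to 0.988 (EGF), 0.642 to 0.939 (morphogen), 0.639 to 0.972 (interferon), 0.766 to 0.972 (leukocyte), 0.761 to 0.988 (glycolysis) and 0.479 to 0.980 (lipid).

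Single genes turned mostly near 0. With the most variable probe set, HNRNPD was at −0.90, ZBTB20 at 0.84, KIF2C at 0.31, PSMB1 at 0.20, CALCA at −0.21, ESR1 at −0.24, PTGS1 at −0.15, VEGFA at 0.084 and TAL1 at −0.044. These other probe sets of HNRNPD, KIF2C, PSMB1 and ESR1 had an unadjusted p under 0.05. With the mean of probe sets, KIF2C was at 0.080, PSMB1 at 0.069, HBEGF at −0.017, ESR1 at −0.039 and MUC1 at 0.022. Without cross-hybridising probe sets, ESR1 was at −0.24, VEGFA at 0.084 and TUBB at −0.060. PTGS2 was at 0.00091 after quantile normalization and 0.00092 with array weights. With arrays left out, the ranges were −0.25 to 0.0028 for P4HB, −0.020 to 0.16 for HBEGF, −0.090 to 0.36 for BMP2, −0.071 to 0.0081 for MSX1, −0.066 to 0.041 for PTGS2, −0.057 to 0.23 for PTGES, −0.24 to 0.00088 for PGR, −0.11 to 0.080 for FKBP5, −0.26 to 0.022 for MUC1, −0.12 to 0.13 for CDH1 and −0.13 to 0.043 for ODC1.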

Other observations

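The scan of gene families, the choice of the genes named here, the tests of smooth muscle genes and the brightness test of nuclear transcripts were chosen after the results were seen.

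Several families of protein folding, cytoskeleton and translation genes were higher at implantation sites, beyond the lists of the report. Subunits of the chaperonin CCT, which folds actin and tubulin, had a median log2 difference of 0.37 over 9 genes, and CCT4 (0.79), CCT8 (0.51) and CCT3 (0.51) rose. CCT8 (means of 3.86 at implantation and 3.35 at interimplantation sites) and CCT3 (3.98 and 3.47) were dim, under the median brightness of 4.19. Alpha-tubulin genes had a median of 0.43 over 6, with TUBA1B (0.99), TUBA1C (0.83) and TUBA4A (0.53) past the threshold, and of 9 beta-tubulin genes TUBB3 (0.89), TUBB4B (0.51) and TUBB (0.48) passed. Tubulin probe sets with near-identical targets may read one another's transcripts, and without cross-hybridising probe sets TUBB was at −0.06. Among 43 genes grouped only by a symbol that starts with EIF, 6 rose and 0 fell, with a median of 0.09. Those that rose included EIF2S2 (0.63), EIF4G2 (0.59) and EIF3I (0.57). With the mean of a gene's probe sets CCT8 (0.29), TUBB (0.28), EIF2S2 (0.25) and EIF4G2 (0.29) did not pass. Over 416 families sharing a symbol stem, camera placed 8 higher and 1 lower (CCT adjusted p = 3.47e-08, EIF adjusted p = 9.88e-06), and 0 held with an estimated correlation. CCT3 missed the threshold without any 1 of 4 arrays (adjusted p up to 0.0747), TUBB4B without any 1 of 5 (up to 0.0751) and after repeated quantile normalization (0.0742), TUBB without any 1 of 3 (up to 0.0713) and TUBA4A without 1 (0.0580).

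Metallothioneins, small metal-binding proteins, were the family that was lower, with a median of −0.29 over 10 genes (camera adjusted p = 0.000301; adjusted p = 0.992 with an estimated correlation). The human probe set for MT1F was 0.63 lower on the log2 scale and was the one that passed, and that for MT2A was at −0.36. MT2A passed after repeated quantile normalization (−0.50, adjusted p = 0.0236), with the stricter filter on brightness (0.0481) and with array weights (0.0483). The metallothionein probe sets were designed on human genes and may read one another's transcripts. The 10 values can therefore not be counted as independent, or as 10 genes of the hamster. The directions of the CCT, tubulin, EIF and metallothionein medians were the same under 3 other scalings of the arrays. IPO7 (0.56), a nuclear import receptor, and XPO1 (0.63), the main export receptor, rose, each lost without any 1 of 5 arrays (adjusted p up to 0.170 and 0.124). The 6 genes named IPO did not pass as a family (median 0.04, camera adjusted p = 0.588). The 6 genes named KPNA did (median 0.23, camera adjusted p = 0.0325), but not with an estimated correlation (adjusted p = 0.992). WT1 (0.74), a transcription factor, rose, while PDGFRA (−0.66), a growth factor receptor, and IGFBP7 (−0.67), which binds insulin-like growth factors, fell. WT1 missed the threshold without 1 of the 6 arrays (adjusted p = 0.0747). KCNMA1, the pore of a calcium-activated potassium channel of smooth muscle, fell by 0.72. With the mean of a gene's probe sets WT1 (0.36), PDGFRA (−0.26), IGFBP7 (−0.25), IPO7 (0.17) and KCNMA1 (−0.22) did not pass.

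A smaller share of muscle in the implantation pieces is a candidate explanation for the falls of ACTG2, TAGLN and MYLK. The test asked whether the bright muscle genes together fell to a median of −0.28 or below. That bound was set from the fall of the 3 genes, which were themselves picked for falling. The median of 15 genes, the 3 included, was 0.021 (95% bootstrap interval −0.135 to 0.128), so these genes did not fall together by that amount. Some muscle genes were lower too, among them TPM2 (−0.47), CNN1 (−0.23) and KCNMA1, as was a dimmer probe set of MYH11 (−0.35). With these 3 and all dimmer muscle genes added, the median of 32 was −0.009 (−0.076 to 0.037), above the same bound. This test cannot decide the question. Some of the 15, such as ACTN1 and LPP, are also expressed outside muscle, and a human probe set that hamster RNA does not bind cannot fall. A smaller share of muscle, as the whole or a part of the cause, stays open. A change within muscle cells stays open too and was not tested.

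Some transcripts of nuclear proteins were lower at implantation sites: SON (−0.66), PNISR (−0.68) and SRSF7 (−0.93), which encode splicing proteins, and ZFC3H1 (−0.49), which acts in RNA decay, fell. WSB1 (−0.41), a subunit of a ubiquitin ligase, fell too. Splicing genes did not fall as a group, since HNRNPD, SRSF1, HNRNPA2B1 and SRSF3 rose. Transcripts such as SON are often held in the nucleus with introns, and a list of similar genes was written before their values were read. Over 33 of them the median was −0.088 (95% bootstrap interval −0.120 to 0.016), 22 were lower and 11 higher, and 0 passed in limma's test over all genes, with 9 lower and 1 higher at an unadjusted p under 0.05; camera gave an unadjusted p of 0.000707, or 0.0177 with an estimated correlation. The listed genes thus shifted down slightly by camera, although the interval of the median includes 0. Whether their transcripts were kept in the nucleus was not measured, so a general fall of such transcripts stays open. A bias by brightness is argued against, since the median lay at percentile 0.02 of random lists matched on brightness. RNA integrity stays open as a cause of the shift. With the actin 3′ to 5′ difference as a covariate the group difference was −0.088, about as large as without the covariate (−0.090). The interval of that difference, from −0.257 to 0.082, includes 0. SON missed the threshold without 1 array (adjusted p = 0.0503), ZFC3H1 without any 1 of 2 (up to 0.0947) and WSB1 without any 1 of 3 (up to 0.0858), and with the mean of a gene's probe sets SON (−0.27), PNISR (−0.31), WSB1 (−0.09) and SRSF7 did not pass.

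Other splits of the arrays bear on the counts. The real split gave 148 genes and 235 probe sets past the threshold, and the highest of the other splits gave 1 of each. It gave 7 gene lists, and the highest other split gave 5. The real split was the 1 of 10 with the largest count in each case, and 10 splits are too few for a share under 0.05. By list, no other split gave a smaller camera p for the proteasome, proliferation and endoplasmic reticulum lists. Splits that mixed the sites still gave these lists an unadjusted camera p down to 2.95e-08, 0.000138 and 0.000553. The real split gave 1.38e-11, 4.70e-10 and 1.56e-05. A small camera p at the preset correlation was thus not particular to the real split. Of the other splits, 2 gave a smaller p for the spliceosome, 2 for the ubiquitin enzymes, 3 for the ribosomal proteins and 2 for oxidative phosphorylation.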
